A study of Mus musculus with 8 samples.

How the data were processed

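Total RNA from mandibular condyles of C57BL/6J mice was measured on Clariom S Mouse arrays, 8 arrays in all. Per the labels' protocols, the head of the mandible with its cartilage and subchondral bone was collected 4 weeks after surgery at 8 weeks of age, cleared of soft tissue, frozen, and extracted with TRIzol before biotin labelling with the WT PLUS kit. The 8 groups cross sex with gonadectomy (ovariectomy or orchiectomy against sham surgery) and with mechanical stress from a metal plate fixed behind the upper incisors, and each group holds 1 array. The labels do not say whether an array carries 1 animal or a pool, so every p-value measures only how far these arrays disagree.

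The deposited values are on a log2 scale, as judged from their range, since the base is not given in the sources used here. Per the submitters' processing notes they were made with Affymetrix Expression Console 1.4 and RMA, which corrects background, normalizes arrays to a common distribution and summarises probes per probe set. Values ran from 1.93 to 19.88, and 1.16% to 1.29% of the values of an array lay above 16, the log2 of the highest 16-bit reading. A rescaling step that would give such values is not given in the sources used here, so differences are given as the deposited scale has them and folds assume log base 2. No array was scaled again for the values reported first.

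The table held 28846 probe sets, of which 6640 were controls, including 5222 intron, 1324 exon and 23 background controls. Of the 22206 gene-level probe sets, 19572 carried 1 gene symbol, 0 carried several, and 2634 were unnamed in the annotation used here and entered only an alternative. Where a symbol had several probe sets, the one with the highest mean was kept, which left out 67 and gave 19505 genes. A gene was tested where it reached the 40th percentile of gene-level probe sets (5.63 to 5.89 by array) on at least 4 of the 8 arrays, which left 11970 genes.

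No group had a replicate array. The effects of stress, gonadectomy and sex were therefore estimated with limma 3.58.1 in R 4.3.3, in an additive fit of sex, gonadectomy and stress over all 8 arrays. Each effect compared 4 arrays with 4, and its error came from the residual of that fit, with 4 degrees of freedom before moderation by eBayes, which holds all interactions between the factors. Matched pairs, arrays alike in the other 2 factors, served to compare directions and, in an alternative, as a block. The effects of stress and gonadectomy within each sex (2 arrays against 2) came from 1 joint fit over all 8 arrays, whose error, with 2 residual degrees of freedom, both sexes share, and each interaction of 2 factors was tested in a fit of its own with 3. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all 11970 genes, and tests were two-sided. Differences are given as log2 values ± SE of the moderated fit.

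Of 31 gene lists fixed before the data were examined, 30 were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 30 lists within an effect, and 1 list of sex-linked genes served as a check of the labels. The 30 covered cartilage matrix, hypertrophic chondrocytes, the superficial zone and synovial lining, tendon and ligament, osteoblasts and osteocytes, osteoclasts, matrix-degrading proteases, inflammatory mediators, apoptosis, Wnt, hedgehog and PTHrP, and TGF-beta and BMP signalling. They further covered mechanosensing, hypoxia and glycolysis, sex steroid receptors, oxidative phosphorylation, the cell cycle, the immediate early, heat shock and interferon responses, and markers of skeletal muscle, erythroid cells, neutrophils, B lymphocytes, T and NK lymphocytes, macrophages, endothelium, adipocytes, nerve and epithelium. The lists named 513 genes in all, of which 43 had no named probe set. Camera with an estimated correlation and fry, which asks whether a list moves on balance one way without comparing it with other genes, were run beside it.

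For each main effect the 10 higher and 10 lower genes with the largest differences were named among those that passed and moved the same way in all 4 pairs; where fewer passed, those with the smallest p filled the places and are said not to have passed. The other fits name up to 5 genes each way, each list up to 4 members, and a set of joint and hormone genes fixed in advance is always given. Of these, Esr2 stayed below the floor. Each treated array was also compared with the control array of its own sex at 2-fold, without a test, and each list's median difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins.

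The steps were tested on simulated data. With 200 of 11970 genes changed over 20 simulations, the stress fit recovered 52.5%, 92.5% and 99.3% of genes changed by 1, 2 and 3 on the log2 scale, and 4.46% of its calls were false. The joint fit, for the effect in females, recovered 0.672%, 52.4% and 82.3%, and the interaction of sex with stress 0.448%, 24% and 63.3%. A list of 15 genes moved by 0.5 was called in 20 of 20 simulations, and 1 of 580 unmoved lists was called. The simulated genes varied independently of one another, whereas the correlation within the real lists was estimated at -0.27 (nerve) to 0.75 (neutrophil). The simulation therefore does not show how often camera calls unmoved lists of correlated genes. It also held no differences of quality or cell content between arrays, so the 4.46% need not hold for the real stress calls.

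The alternatives were no floor, a floor at the 60th percentile, all gene-level probe sets, median centring, another quantile normalization, eBayes with an intensity trend or made robust, array weights, matched pairs as a block, no covariates, the skeletal muscle or the marrow lists' mean per array as a covariate, a fold threshold beside the p, leaving out each array in turn, and other fold thresholds for single arrays. The median of the intron control probe sets as a covariate was added after seeing the data.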

Results

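Gene expression was measured in the mandibular condyle, the jaw's side of the temporomandibular joint, in 4 female and 4 male groups of 12-week-old mice: sham-operated controls, mechanical stress, gonadectomy, and both together. Each group was a single array. Median log2 signal lay between 6.61 and 6.64 on every array, and the interquartile range between 4.45 and 5.07. The Y-linked gene Eif2s3y, a translation factor subunit, read 11.89 to 12.19 on the male arrays and 2.76 to 3.84 on the female arrays, so the arrays matched their sex labels. The first principal component held 30.8% of the variance and parted the 4 stress arrays (11.8 to 40.7) from the 4 others (-30.5 to -8.29), and the second held 20.8%. The female stress array stood furthest from the rest, with a mean correlation of 0.970 with the other arrays and an array weight of 0.397.

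The first comparison asked what excessive load on the joint did to the condyle, over both sexes, with and without gonadectomy. Angptl7, a secreted angiopoietin-like protein, rose by 3.68 ± 0.46 on the log2 scale (12.8-fold, adjusted p = 0.031, 4 arrays against 4), the largest rise among the called genes. Over 21 alternatives its difference ran from 2.45 to 6.00, and it passed in 13. Car1, the carbonic anhydrase of red cells, rose 6.99-fold (2.81 ± 0.25, adjusted p = 0.0079), and Serpina3n, a secreted inhibitor of serine proteases, rose 6.02-fold (2.59 ± 0.27, adjusted p = 0.014). Prg4, which encodes the joint lubricant lubricin, rose 2.34-fold (1.23 ± 0.23, adjusted p = 0.043). Over 21 alternatives Prg4 passed in 8, against 17 for Car1 and 17 for Serpina3n. The steepest fall was that of Myh4, the myosin heavy chain of fast IIb muscle fibres, which fell by 2.60 ± 0.33 on the log2 scale (6.07-fold, adjusted p = 0.031).

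Ankrd2, a stretch-responsive ankyrin repeat protein, rose by 3.07 ± 0.48, Myoz2, a Z-disc protein of slow and cardiac fibres, by 2.56 ± 0.41, and Abra, an actin-binding protein of striated muscle, by 2.33 ± 0.44. Lrrc2 rose by 2.20, Popdc3 by 2.15, Csrp3, the muscle LIM protein, by 2.12, and Casq2, a calcium store of the sarcoplasmic reticulum, by 2.11. Among the falls, Actn3, the alpha-actinin of fast fibres, fell by 1.85 ± 0.24, as did Kera, a small proteoglycan of tendon and cornea, by 1.85 ± 0.31. Shisa5 fell by 1.85, Mylk, a myosin light chain kinase, by 1.70, Pdzrn4 by 1.53, Dlx5, a transcription factor of bone formation, by 1.51, and Mfap2, a microfibril protein, by 1.49. Npas2, a transcription factor of the circadian clock, fell by 1.45 and Tmem107, a protein of the primary cilium, by 1.41. Over the 21 alternatives, Abra and Pdzrn4 passed in 7 each, Npas2 in 6 and Tmem107 in 5, against 15 for Actn3 and 13 for Casq2. The difference of Ankrd2 ran from 2.41 to 5.68 and that of Actn3 from -2.54 to -0.927.

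**Figure D1:**
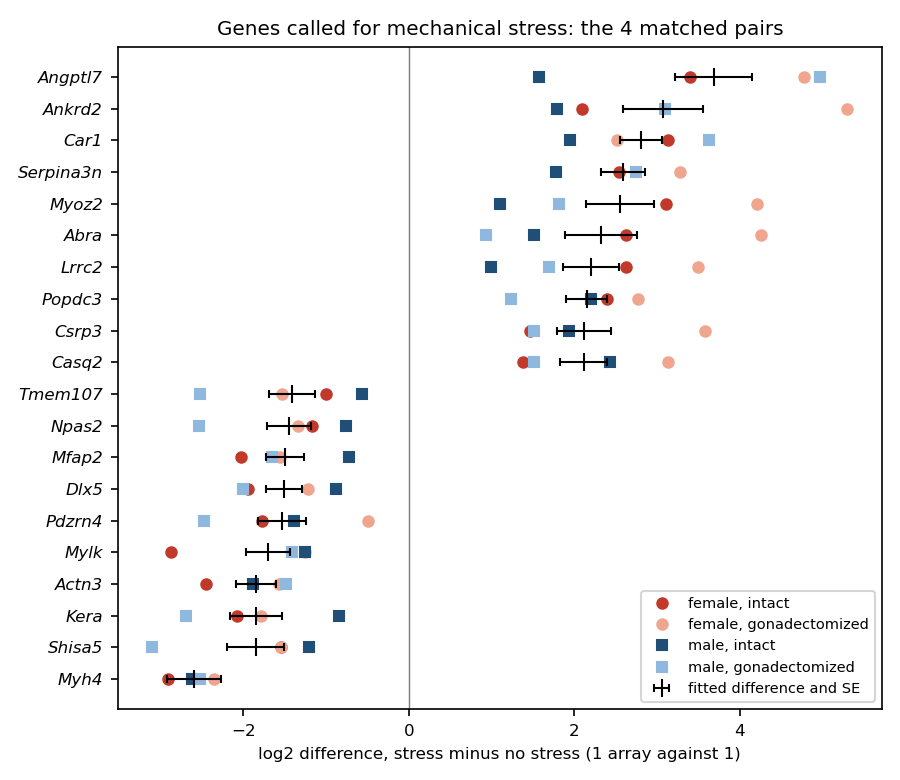
Log2 difference, stress minus no stress, of the 10 higher and 10 lower genes named for mechanical stress, with 1 point per matched pair of arrays and the fitted difference with its SE. All 4 pairs lie on the same side of 0 for every gene shown, from Angptl7 at 3.68 to Myh4 at -2.60.

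Of 11970 genes, limma called 132, of which 72 (54.5%) were higher and 60 lower under stress, and all 132 moved the same way in the 4 pairs. At an unadjusted p under 0.05 there were 2346 genes, against 598 by chance, and 28.6% of all genes had the same sign in the 4 pairs against 12.5% by chance. Other scalings moved the split to 67.1% higher (108 of 161, arrays centred on the median) and to 64.7% higher (86 of 133, quantile normalization again). The count rested on single arrays: it was 3 without the female control, 6 without the female stress array, 0 without the ovariectomized female, 9 without the ovariectomized female under stress, 6 without the orchiectomized male and 0 without the orchiectomized male under stress, but 113 without the male control and 124 without the male stress array. It was 2 with the median of the intron control probe sets as a covariate, a measure of signal from unspliced RNA or DNA that averaged 6.45 ± 0.03 on the stress arrays and 6.57 ± 0.04 on the others (SD, n = 4 each, exact permutation p = 0.0286, adjusted p = 0.3 over 21 such tests, over all 70 assignments of the arrays, which disregard the other 2 factors), 38 with matched pairs as a block, 0 with the marrow lists and 22 with the skeletal muscle list as a covariate. The labelling controls parted the stress arrays as fully (6.33 against 6.84, exact permutation p = 0.0286, adjusted p = 0.3), and the exon controls averaged 10.20 against 10.37 (exact permutation p = 0.0857, adjusted p = 0.36). An exact permutation p of 0.0286 is the smallest that 70 assignments allow. The adjusted values therefore do not show that the stress arrays were like the others in quality.

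Of the 30 gene lists, 6 were called for stress, 5 higher and 1 lower. The erythroid list had a mean difference of 1.41 ± 0.66 (SD over 9 genes), all 9 above 0. Its members Car1, Ermap (1.65), a red cell adhesion protein, and Rhag (1.63), of the Rh complex, rose among all genes, and 9 passed when adjusted over the list alone. Hemgn, at 1.79, did not pass over all genes. Neutrophil genes averaged 0.90 ± 0.36, with 14 of 14 above 0, among them Camp (1.58), Elane (1.47), Ctsg (1.31) and Fcnb (1.20), but 0 passed over all genes or adjusted over the list alone. The neutrophil mean was 0.37 without the orchiectomized male, the array that read lowest for these genes, and -0.90 with the marrow lists, which include them, as a covariate, where the erythroid mean was 0.65. Oxidative phosphorylation genes averaged 0.38 ± 0.34, with 19 of 22 above 0, where 0 passed over all genes and 6 when adjusted over the list alone, including Cox8b (0.89), Ndufv1 (0.88), Cox7a1 (0.87) and Cox6a2 (0.85). Their mean was 0.25 without the ovariectomized female under stress. Camera gave adjusted p = 1.2e-09 for erythroid, 2.9e-05 for neutrophil and 1.4e-05 for oxidative phosphorylation genes. All of these calls were lost in the stricter test, at adjusted p = 0.60 with an estimated correlation for erythroid and oxidative phosphorylation genes and adjusted p = 0.64 with an estimated correlation for neutrophil genes.

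The skeletal muscle list moved in both directions. Its mean was 0.18 ± 0.94 and its median 0.36 over 24 genes, with 20 above 0. Mybpc1, a myosin-binding protein of slow fibres, rose by 1.39, while Myh4, Actn3 and Pvalb, the calcium buffer of fast fibres, fell by 2.60, 1.85 and 1.07, and 20 genes did not pass over all genes. Adjusted over the list alone, 8 were higher, including Myh2 (1.04) and Mb (0.96), and 4 lower (camera adjusted p = 0.0095, but adjusted p = 0.86 with an estimated correlation). The call ended without the ovariectomized female (mean 0.01), without the ovariectomized female under stress (mean -0.06), with no covariates, and with the marrow lists or the list's own mean as a covariate, while the mean was 0.29 without the female stress array and 0.32 without the male control.

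B lymphocyte genes averaged 0.29 ± 0.53 under stress, with 7 of 11 above 0. Ms4a1, the B cell antigen CD20, rose by 1.43 and was the 1 member called over all genes, with 2 when adjusted over the list alone (adjusted p = 0.039, but adjusted p = 0.60 with an estimated correlation). Hedgehog and PTHrP signalling genes averaged -0.33 ± 0.36, with 10 of 11 below 0. Gli3, a transcription factor of the hedgehog pathway, fell by 0.90 over all genes, and 5 passed when adjusted over the list alone, including Pth1r (-0.69), the PTHrP receptor, Hhip (-0.68) and Gli1 (-0.53). That list had adjusted p = 0.047 with camera and 0.01 with fry, but adjusted p = 0.60 with an estimated correlation. The B lymphocyte call ended without the male control (0.17), the male stress array (0.14) or the orchiectomized male (0.26), and the hedgehog call without any of those or the ovariectomized female or the orchiectomized male under stress (-0.34 to -0.32). Both calls also ended with matched pairs as a block, with arrays centred on the median, with no covariates and with the marrow lists as a covariate, and the B lymphocyte call with either other floor (0.19 at the 60th percentile), where the hedgehog mean was -0.52 at the 60th percentile.

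Of the joint and hormone genes fixed in advance, Prg4 alone passed for stress, though in only 8 of the 21 alternatives. Col2a1, the main collagen of cartilage, differed by -1.54 ± 0.47 (adjusted p = 0.12), Col1a1, that of bone, by -0.80 ± 0.17 (adjusted p = 0.059), Col10a1, of hypertrophic cartilage, by 0.70 ± 0.19 (adjusted p = 0.094), and Vegfa by -0.58 ± 0.17 (adjusted p = 0.11), which did not pass. Acan, the core protein of aggrecan, differed by -0.18, the collagenase Mmp13 by 0.09 and the aggrecanase Adamts5 by -0.07. The osteoclast genes Ctsk and Acp5 differed by 0.14 and 0.21, the regulators of osteoclast formation Tnfrsf11b and Tnfsf11 by -0.24 and -0.23, the death receptor Fas by 0.28 and the estrogen receptor Esr1 by -0.33, with adjusted p from 0.39 to 0.90.

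The lists of these tissues were not called for stress. Cartilage matrix genes averaged -0.28 (10 of 15 below 0), hypertrophic chondrocyte genes -0.27, osteoblast and osteocyte genes -0.28 (adjusted p = 0.077), tendon and ligament genes -0.21, proteases -0.17 and osteoclast genes -0.08, the last with a median of 0.04. Within them Mmp3, a stromelysin, fell by 1.16 over all genes. Superficial zone and synovial lining genes averaged 0.24 (adjusted p = 0.074), where Prg4 rose and 3 were higher and 1 lower when adjusted over the list alone. TGF-beta and BMP genes averaged -0.20, Wnt genes -0.07, apoptosis genes -0.17, inflammatory mediators 0.09 and mechanosensing genes 0.07, the last with a median of -0.04.

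Among the remaining lists not called for stress, sex steroid genes averaged -0.03, though Fkbp5, a chaperone of steroid receptors induced by glucocorticoids, rose by 1.70, and hypoxia and glycolysis genes 0.01, with a median and a test on the other side of 0, though Egln3, an oxygen sensor, rose by 1.63. Immediate early genes averaged 0.01 with a median of -0.13, though Dusp1, a phosphatase of MAP kinases, rose by 1.44. Heat shock genes averaged 0.03, interferon genes -0.10, T and NK lymphocyte genes 0.24, macrophage genes 0.11, adipocyte genes 0.22, nerve genes -0.16 and epithelial genes 0.35 over 2 members. Cell cycle genes had a median of 0.08 with a mean just below 0, and endothelial genes a mean of -0.03 with a median of 0.06.

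**Figure D2:**
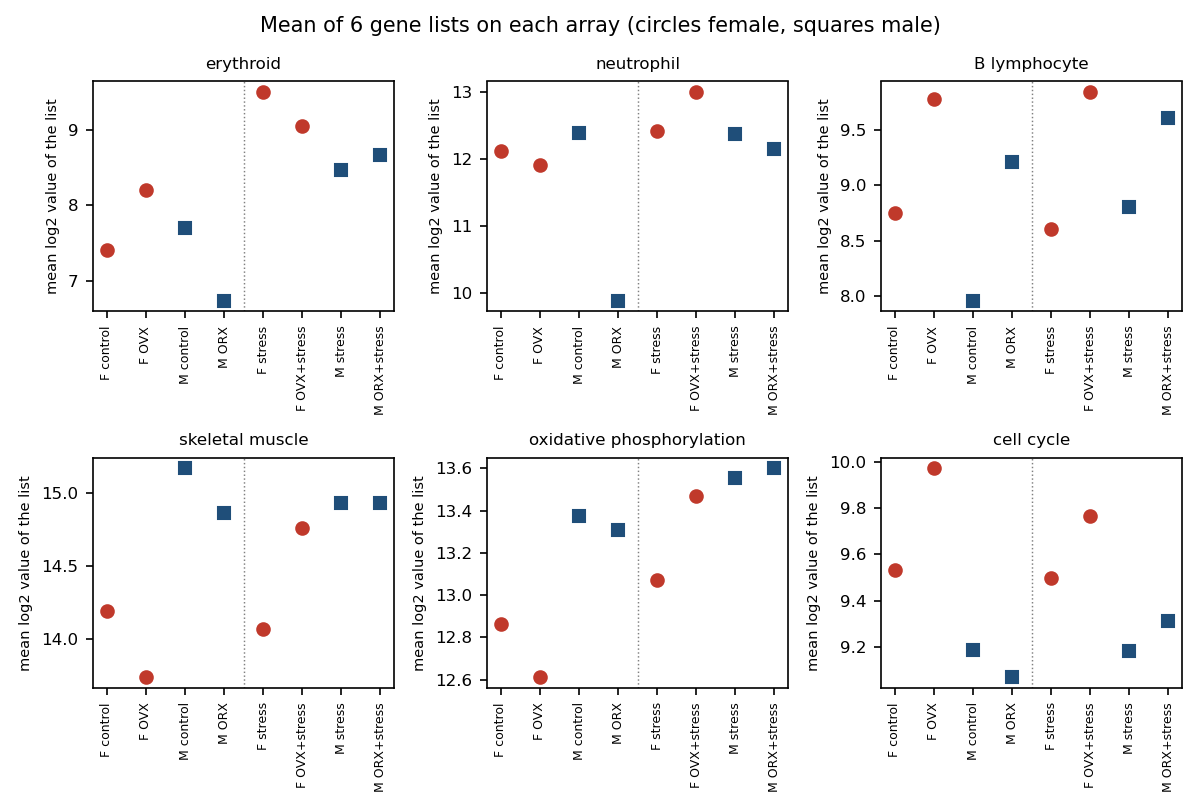
Mean log2 signal of 6 gene lists on each of the 8 arrays (circles female, squares male), with the 4 arrays without stress left of the dotted line and the 4 with stress right of it. Erythroid genes read 6.74 to 8.21 without stress and 8.47 to 9.50 with it, and neutrophil genes were lowest on the array of the orchiectomized male at 9.89.

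**Figure D3:**
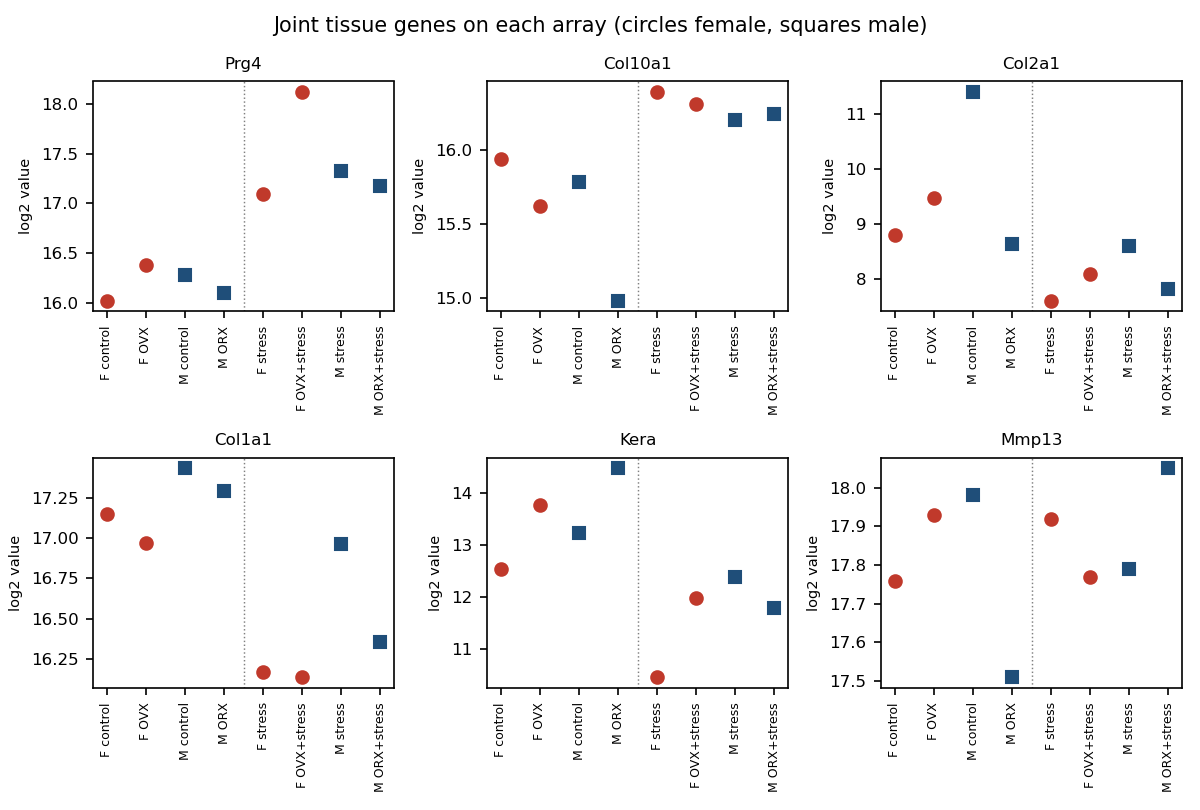
Log2 signal of Prg4, Col10a1, Col2a1, Col1a1, Kera and Mmp13 on each of the 8 arrays (circles female, squares male; arrays without stress left of the dotted line). Prg4 averaged 17.42 with stress and 16.20 without, Kera 11.66 and 13.51, and Mmp13 17.88 and 17.79.

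The second comparison asked what loss of the gonads did over both sexes. B lymphocyte genes averaged 1.08 ± 0.54 (SD over 11 genes) above the sham-operated arrays, with all 11 above 0 and every one of the 4 pairs between 0.80 and 1.26. Cd79a, a chain of the B cell receptor complex, differed by 1.66 ± 0.26, Tnfrsf13c, the receptor for the B cell survival factor BAFF, by 1.86 ± 0.30, and Il7r, the receptor for interleukin 7, by 1.47 ± 0.28. Clock genes stood beside them, with Dbp at 2.13 ± 0.36 and Per3 at 1.44 ± 0.27, while Arntl, their transcriptional activator, lay at -1.15 ± 0.23. None of these genes passed over all genes, with adjusted p from 0.27 to 0.30.

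The other named genes did not pass either. On the higher side stood Ly6d (1.34), a marker of lymphoid progenitors, Ikzf3 (1.23), a lymphoid transcription factor, Ms4a1 (1.11), the clock repressor Nr1d2 (1.10) and Htra4 (0.92). On the lower side stood Pcx (-1.48), the pyruvate carboxylase, Dio2 (-1.21), which activates thyroid hormone, Nfil3 (-1.11), Crispld2 (-1.09), Fgfr3 (-1.08), a receptor that restrains cartilage growth, Sytl5 (-1.04), Mpp4 (-1.02), Sost (-0.99), the osteocyte's inhibitor of Wnt signalling, and Cercam (-0.81).

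Of the 11970 genes, limma called 0 for gonadectomy, at a smallest adjusted p of 0.27. There were 878 at an unadjusted p under 0.05 against 598 by chance, and 16.1% had the same sign in the 4 pairs against 12.5% by chance. The count stayed at 0 with every alternative run on it except without the female stress array, where 1 gene, Pcx, fell (adjusted p = 0.037, against 0.098 to 0.99 in the others).

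Among the lists, 6 were called. For B lymphocytes, 0 of 11 members passed over all genes and 9 when adjusted over the list alone, including Fcrla (1.76) and Vpreb3 (1.73), a part of the pre-B cell receptor (camera adjusted p = 8.7e-14, fry 0.02). The call was lost at adjusted p = 0.11 with an estimated correlation. T and NK lymphocyte genes averaged 0.48 ± 0.61, with 6 of 8 above 0, 0 passing over all genes and 3 when adjusted over the list alone, namely Il7r, Klrb1c (1.10), a receptor of NK cells, and Gzma (0.53), a granzyme (camera adjusted p = 0.0014, fry 0.02, but adjusted p = 0.25 with an estimated correlation). Both lists stayed called whichever single array was left out, but the T and NK mean was 0.21 with no floor and 0.785 with the 60th percentile floor.

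The 4 lower lists rested on few arrays. Neutrophil genes averaged -0.59 ± 0.40, with 14 of 14 below 0, led by Camp (-1.23) and Ltf (-1.04), but the call ended without the orchiectomized male (-0.06) or the male control (-0.17), and the mean was -0.99 with array weights and -0.94 without the female stress array. Adipocyte genes averaged -0.49 ± 0.47, with Retn, the hormone resistin, at -1.45 and Cidec at -0.85, and the call ended without the female control (-0.04), the ovariectomized female (-0.29) or the ovariectomized female under stress (-0.43), with a mean of -0.81 without the orchiectomized male under stress. Heat shock genes averaged -0.28 ± 0.24, led by Hsph1 (-0.73), until the ovariectomized female, the male control, the male stress array or the orchiectomized male under stress was left out (-0.20 to -0.06), and averaged -0.43 without the female stress array and -0.57 without the ovariectomized female under stress. Hypoxia and glycolysis genes averaged -0.21 ± 0.26, led by the glucose transporter Slc2a1 (-0.67), until the ovariectomized female (-0.12) or the male control (-0.16) was left out. In these 4 lists 0 members passed over all genes or adjusted over the list alone. Camera gave adjusted p = 0.00085, 0.0077, 0.019 and 0.0051 in that order, while the values were adjusted p = 0.59 with an estimated correlation for the first 3 lists and adjusted p = 0.53 with an estimated correlation for hypoxia and glycolysis.

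The other 24 lists averaged between -0.37 and 0.22 and were not called, with signs of mean, median and test that differed for osteoclast, inflammatory, macrophage and endothelial genes. Fry alone called the nerve list (0.22, adjusted p = 0.02). Cartilage matrix genes averaged -0.11 and osteoblast and osteocyte genes -0.16. Of the joint and hormone genes, Col2a1 differed by -0.60, Acan by -0.43, Tnfsf11 by -0.42, Vegfa by -0.31, Col10a1 by -0.29, Col1a1 by -0.24, Mmp13 by -0.05 and Acp5 by -0.02. Esr1 differed by 0.62, Prg4 by 0.27, Adamts5 by 0.22, Fas by 0.20, Tnfrsf11b by 0.09 and Ctsk by 0.03, with adjusted p of 0.69 or more throughout. Across the 11970 genes the effects of stress and gonadectomy correlated at -0.126, where both effects come from the same 8 arrays.

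**Figure D4:**
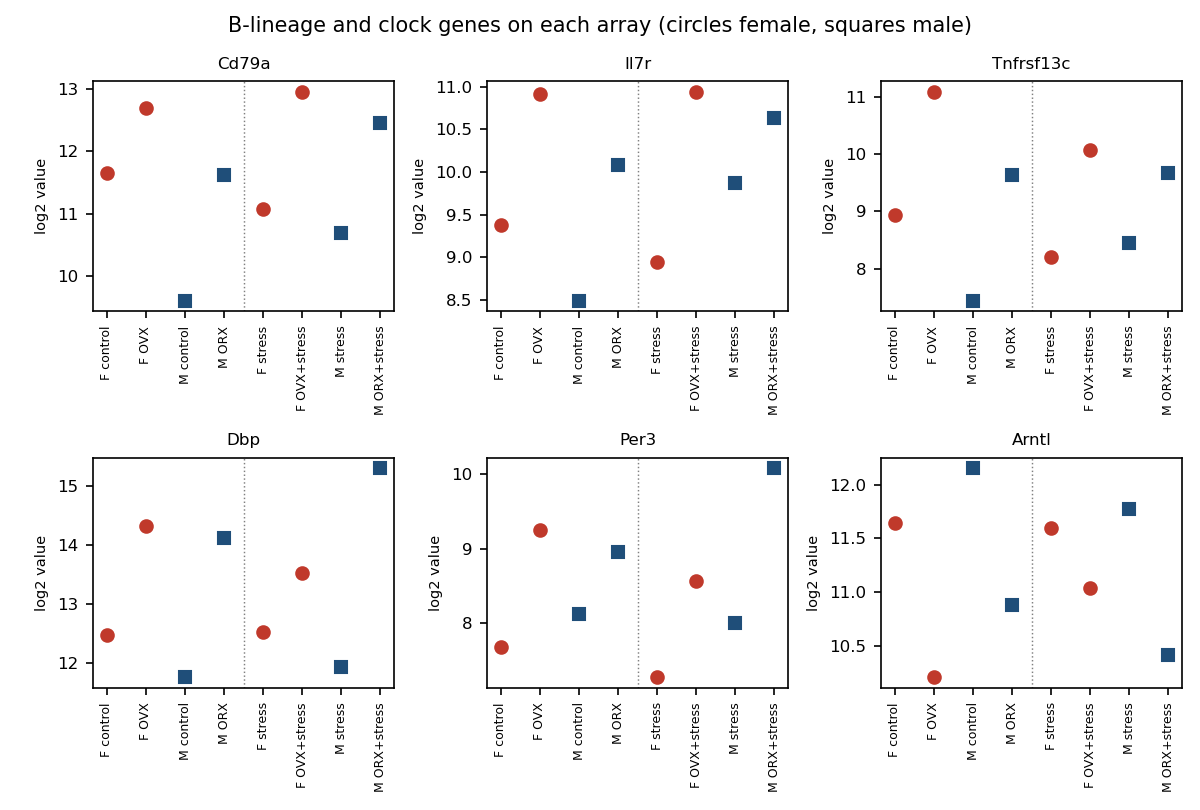
Log2 signal of Cd79a, Il7r, Tnfrsf13c, Dbp, Per3 and Arntl on each of the 8 arrays (circles female, squares male; arrays without stress left of the dotted line). Cd79a averaged 12.43 after gonadectomy and 10.76 after sham surgery, and Arntl 10.64 and 11.79.

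The third comparison set the 4 female arrays against the 4 male arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d differed by -8.93 ± 0.22, -7.97 ± 0.22 and -5.47 ± 0.22. Csf3r, the receptor for the neutrophil growth factor G-CSF, was higher in females by 1.53 ± 0.19 (2.88-fold, adjusted p = 0.03), and Kdm6a, an X-linked histone demethylase that escapes X inactivation, by 1.23 ± 0.17 (2.35-fold, adjusted p = 0.041). Lmod2, an actin filament nucleator of muscle, fell by 1.77 ± 0.23 in females against males (3.41-fold, adjusted p = 0.036).

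Limma called 7 genes, 2 higher and 5 lower in females, with 1379 at an unadjusted p under 0.05 against 598 by chance; the remaining one was the predicted Y-linked gene Gm20823, named here after its values were seen. The count was 3 without the female control, the ovariectomized female or any of the 4 male arrays, and 17 without the ovariectomized female under stress. Other named genes did not pass. They were Bin2 (1.32), Itgal (1.26), an integrin of leukocytes, Adgre4 (1.11), Plcb2 (1.10), Cx3cr1 (0.96), Mcm3 (0.94), Eif2s3x (0.91) and Pbdc1 (0.91) on the higher side. On the lower side they were Map3k7cl (-1.72), Art1 (-1.23), Capn3 (-1.13), a muscle protease, Hspb3 (-1.07), Col16a1 (-1.06) and the eosinophil chemokine Ccl11 (-1.01). The joint and hormone genes differed by -0.63 (Col2a1) to 0.30 (Acp5), with adjusted p of 0.30 or more.

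Of the lists, 10 were called for sex, and all were lost with an estimated correlation. Skeletal muscle genes averaged -0.78 ± 0.27 in females against males, with 24 of 24 below 0 and 20 passing when adjusted over the list alone, led by Ryr1 (-1.43), the calcium release channel, Cacna1s (-1.18), Myh4 (-1.16) and Mybpc1 (-1.05). The list had adjusted p = 2.6e-17 but adjusted p = 0.39 with an estimated correlation. Oxidative phosphorylation genes averaged -0.46 ± 0.33, with 22 of 22 below 0 and 4 passing when adjusted over the list alone, led by Cox8b (-1.39) and Cox7a1 (-1.21) (adjusted p = 4e-09, but adjusted p = 0.39 with an estimated correlation). Their call ended with the skeletal muscle list as a covariate, at a mean of -0.03. Hedgehog and PTHrP genes averaged -0.25 ± 0.19, led by Ihh (-0.64), with 0 passing when adjusted over the list alone (adjusted p = 0.011, fry 0.015, but adjusted p = 0.39 with an estimated correlation). That call ended without the orchiectomized male (-0.25) and with the skeletal muscle list (-0.19) or the marrow lists (-0.25) as a covariate.

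Cell cycle genes averaged 0.51 ± 0.25 above males, with 19 of 19 above 0 and 8 passing when adjusted over the list alone, led by Mcm3, a part of the replicative helicase, Rrm2 (0.82) and Plk1 (0.82) (adjusted p = 5.2e-10, but adjusted p = 0.39 with an estimated correlation). Macrophage genes averaged 0.38 (adjusted p = 0.00012, but adjusted p = 0.39 with an estimated correlation), led by Cx3cr1, the 1 member passing when adjusted over the list alone. Osteoclast genes averaged 0.30 (adjusted p = 0.002, but adjusted p = 0.42 with an estimated correlation), led by Car2 (1.06) and Dcstamp (0.65), with 0 passing on either adjustment. Erythroid genes averaged 0.65 (adjusted p = 0.00069, but adjusted p = 0.51 with an estimated correlation), with 3 passing when adjusted over the list alone, led by Ermap (1.43).

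Neutrophil genes averaged 0.66 (adjusted p = 0.00077, but adjusted p = 0.69 with an estimated correlation), with 1 passing when adjusted over the list alone, Mpo (1.85), the myeloperoxidase. Their call ended without the orchiectomized male, at 0.13, and the mean was 0.42 without the ovariectomized female under stress, 1.01 without the female stress array, 1.09 without the male control and 1.41 with the skeletal muscle list as a covariate. B lymphocyte genes averaged 0.35 (adjusted p = 0.0052, but adjusted p = 0.39 with an estimated correlation), with 2 passing when adjusted over the list alone, Cd79a (0.998) and Bank1 (0.76), until the ovariectomized female was left out (0.28) or the fit had no covariates, with a mean of 0.22 without the male control. Interferon genes averaged 0.34 (adjusted p = 0.012, but adjusted p = 0.51 with an estimated correlation), with 2 passing when adjusted over the list alone, Rsad2 (0.97) and Oasl2 (0.63). That call ended without the female stress array (0.30), the male stress array (0.28) or the orchiectomized male (0.28) and with the higher floor (-0.02). With the skeletal muscle list as a covariate the erythroid (0.42), osteoclast, B lymphocyte (0.14) and interferon (0.08) calls ended, and with the marrow lists these (erythroid 0.17, osteoclast 0.19) and the macrophage call (0.14), while the neutrophil mean became -0.49 and the cell cycle mean 0.28. Over all genes, limma called 0 members of the 10 lists. The other 20 lists averaged -0.27 to 0.30, with signs of mean, median and test that differed for osteoblast and osteocyte, protease, nerve and epithelial genes.

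Within females, stress raised Myoz2 by 3.66 ± 0.34, Myl2, the regulatory myosin light chain of slow and cardiac muscle, by 3.60 ± 0.34, and Lrrc2 by 3.06 ± 0.32, while Myh4 fell by 2.64 ± 0.27 (adjusted p = 0.042 each, 2 arrays against 2). Abra (3.44) and Serpina3n (2.91) on the higher side and Actn3 (-2.01), Pla2g2d (-1.94), Ccser1 (-1.88) and the interferon-induced Ifit1 (-1.60) on the lower did not pass. In males Car1 differed by 2.79, Prg2, the major basic protein of eosinophils, by 2.36, Serpina3n by 2.27, the adipocyte hormone Adipoq by 1.82, and Slc2a3 by 1.56. Myh4 differed by -2.57, Shisa5 by -2.15, Actn3 by -1.69, Crtc3 by -1.47 and Tpcn1 by -1.31 in males, and none of these passed (adjusted p = 0.16 or more). Limma called 4 genes for stress in females (1830 at an unadjusted p under 0.05) and 0 in males (956, against 598 by chance). The female count was 0 without a floor, over all probe sets or with array weights, and 43 with the higher floor, and the male count was 4 with an intensity trend and 1 with array weights.

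After ovariectomy the higher genes named by smallest p were Ccdc18 (2.05), Tnfrsf13c (2.005), Il7r (1.77), Il2ra (1.63) and Stfa2l1 (1.61). Ucp1, the uncoupling protein of brown fat, lay at -3.48 ± 0.62, the protease inhibitor A2m at -2.64, Fasn, the fatty acid synthase, at -2.41, Iigp1 at -1.68 and Xlr3b at -1.24. After orchiectomy Dbp differed by 2.85 ± 0.34, Nr1d1, a clock repressor, by 1.96, Cd79a by 1.88, Dixdc1 by 1.76 and Cage1 by 1.52. Mrgpra2b lay at -2.32, Mrgpra2a at -2.28, Myl2 at -2.13, Fgfr3 at -1.51 and Nfil3 at -1.48. None passed, and limma called 0 genes for ovariectomy (800 at an unadjusted p under 0.05) and 0 for orchiectomy (519; 1 with an intensity trend).

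The tests of whether effects differed between groups called 0 genes as well, so the genes named for them are those with the smallest p, not the largest differences. For sex by stress there were 577 genes at an unadjusted p under 0.05, with Ppp1r3c (2.79), Perm1 (2.31), Myoz2 (2.20), Trim63 (2.07), a ubiquitin ligase of muscle wasting, and Asb14 (1.47) higher and Smagp (-1.84), Ifit1 (-1.71), Zfp945 (-1.68), Tmem191c (-1.62) and Bag4 (-1.51) lower in females than in males (adjusted p = 0.95). For sex by gonadectomy there were 495, from Mrgpra2b (3.08), Mrgpra2a (2.79), Stfa2l1 (2.34), Myh4 (1.76) and Mctp1 (1.76) to Qtrt1 (-1.51), Cage1 (-1.53), Tram1l1 (-1.61), Hmgcs1 (-1.90) and Ucp1 (-5.51) (adjusted p = 1). For gonadectomy by stress there were 758, from Mup19 (2.73), Fbp2 (2.68), Hp (2.38), haptoglobin, Adh1 (2.21) and Dpep1 (1.82) to Hoxb2 (-1.43), Lrriq3 (-1.43), Stmn3 (-1.50), Gpr75 (-1.58) and Btbd35f3 (-1.75) (adjusted p = 0.76). The effects within each sex came from 1 fit with an error shared by both sexes. Leaving out single arrays of either sex left it 1 residual degree of freedom, and the counts then ran from 172 to 697 for stress in females, 9 to 92 in males, 13 to 167 for ovariectomy and 1 to 28 for orchiectomy.

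Set against the control of its own sex, each treated array stands without a replicate check, and values are single differences. In the female stress array 2093 of 12646 genes lay past 2-fold (863 higher, 1230 lower), from the lacrimal and salivary gland genes Mucl2 (5.13) and Prol1 (4.81), through Myl2 (3.55), Angptl7 (3.41) and Ctse (3.32), to Fasn (-3.03), Mup19 (-3.25), Thrsp (-3.42), Ucp1 (-3.89) and Cxcl9 (-4.32). The labelling controls of that array averaged 5.60, against 6.45 to 6.95 on the others. Its exon control median (10.02) was the lowest and its background control median (6.17) the highest of all arrays. Its count is therefore no measure of a stronger response to stress in females, and the part due to array quality was not tested. The ovariectomized female had 613 genes past 2-fold (311 higher, 302 lower), from Ipw (3.15), Ppbp (2.77), a platelet chemokine, Speer4c (2.33), Btbd35f4 (2.21) and Tnfrsf13c (2.16) to Pck1 (-3.33), Fasn (-3.58), A2m (-3.70), Thrsp (-3.90) and Cxcl9 (-4.89). Both treatments together gave 874 in females (474 higher, 400 lower), from Angptl7 (5.44), Myl2 (3.90), Ankrd2 (3.67), Car1 (3.31) and Abra (3.28) to Pck1 (-2.99), Thrsp (-3.43), Fasn (-4.27), A2m (-4.49) and Cxcl9 (-6.00). The shared female control read 11.75 for Cxcl9, an interferon-induced chemokine, and enters all of these differences.

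In males, stress gave 415 genes past 2-fold (229 higher, 186 lower), from Prg2 (3.11), Ear6 (2.76), a ribonuclease of eosinophils, Casq2 (2.43), Popdc3 (2.20) and Myl2 (2.15) to Myh4 (-2.61), Col2a1 (-2.79), Krt10 (-2.84), Pkp1 (-3.45) and Ada (-4.18). Orchiectomy gave 412 (159 higher, 253 lower), from Dbp (2.36), Nr1d1 (2.31), Vpreb3 (2.24), Tnfrsf13c (2.21) and Cd79b (2.04) to S100a9 (-3.24), Chil4 (-3.63), Ada (-4.15), Chil3 (-4.17) and Camp (-4.90). Both together gave 976 (459 higher, 517 lower), from Angptl7 (4.28), Dbp (3.54), Car1 (3.21), Cd79b (2.96) and Cirbp (2.88) to Myh4 (-3.43), Ada (-3.50), Pkp1 (-3.51), Col2a1 (-3.58) and Serpinb3c (-3.66). The shared male control read 10.91 for Ada, where the treated males read 6.73 to 7.41, and enters all of these differences. It read 9.80 for Pkp1 against 6.35 under stress and 6.29 with both treatments, and 11.4 for Col2a1 against 8.60 and 7.82.

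By list, the median difference of the B lymphocyte genes was 1.03 in the ovariectomized female and 1.05 with stress added, and 0.92 in the orchiectomized male and 1.30 with stress added. In the stress arrays it was 1 in the male and -0.06 in the female. The differences within a sex share 1 control array, so they are not independent, and the male control read lowest of all 8 arrays for this list (7.96). Erythroid genes stood at 2.36, 0.80 and 1.45 in the female under stress, ovariectomized and with both, and at 0.59, -0.71 and 0.72 in the male under stress, orchiectomized and with both. All of these lay at percentile 99.98 or higher of random lists except the orchiectomized male at percentile 0, so extreme percentiles also came without stress and on both sides. Adipocyte genes stood at -0.96, -1.86 and -1.29 in the 3 treated females, all against a female control that read 10.91 where those arrays read 9.13 to 9.86, at 0.34 in the male stress array, at -0.06 in the orchiectomized male and at 0.75 with stress added. Neutrophil genes stood at -2.56 in the orchiectomized male, at percentile 0.

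Across genes, which are not independent replicates, the 4 disjoint pairs of arrays that measure an effect resembled one another most for stress. Their log2 differences correlated at 0.236 to 0.402 for stress, 0.022 to 0.153 for gonadectomy and 0.133 to 0.345 for sex, over 6 pairs of pairs each.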

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

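The interaction tests and the fit over all gene-level probe sets were chosen before the data were examined; the comparison of the number of opposite effects with chance was made after their values were seen.

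Probe sets without a gene name in the annotation used here held signal that no comparison of named genes covers. With 1415 of 2634 such probe sets at the floor, limma called 7 for stress (2 higher, 5 lower, from 1.76 to -1.57 on the log2 scale), 9 for sex (all lower in females, down to -8.03) and 0 for gonadectomy, where 8 lay past 2-fold.

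In 17 cases, over 15 genes or lists, an effect went one way in every pair of one group and the other way in every pair of the other, with 2 pairs on each side. Of 120 combinations of list and contrast, 10 did so, against 15 expected by chance. Acp5 and the skeletal muscle list each make up 2 of the cases with the same values, since stress by gonadectomy and gonadectomy by stress are 1 interaction. The gene differences were tested as interactions and none passed; the list differences were not tested.

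Acan differed under stress by 0.66 more in females than in males (adjusted p = 0.95). Without gonadectomy, compared with after it, the effect of stress differed by -0.80 for Adamts5 (adjusted p = 0.80), by -0.37 for Ctsk (0.88) and by -0.59 for Acp5 (0.80), by -0.24 for the sex steroid list and by -0.73 for the skeletal muscle list. The effect of gonadectomy was 2.35 higher in females than in males for Col2a1 and 0.86 higher for Prg4 (adjusted p = 1 for each), 0.17 higher for inflammatory mediators, and differed by -0.88 for the 2 epithelial genes. Without stress, compared with under it, the effect of gonadectomy differed by -0.31 for cartilage matrix, -0.30 for osteoclast, -0.38 for oxidative phosphorylation, -0.73 for skeletal muscle, -0.45 for macrophage and -0.36 for endothelial genes, and by -0.59 for Acp5.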

How the results depend on the processing

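One alternative, the median of the intron control probe sets per array as a covariate, was chosen after the results were seen; all others were chosen before the data were examined. As to replicate numbers, no paired analysis was possible because the labels carry none and each group has 1 array; arrays alike in 2 factors were paired by the design itself in the matched-pair block, an alternative with 3 residual degrees of freedom. The number of genes called is the least stable kind of result, while the direction of the named genes and lists mostly held. For genes named by the rule this is in part built in, since they were chosen for the same sign in all 4 pairs. Over the alternatives chosen beforehand, the differences of named genes kept direction and side of the threshold 1478 times, kept only the direction 229 times (no longer passing) and 17 times (newly passing), and changed direction 22 times; for the called lists these were 365, 93, 0 and 4. With the covariate added later they were 64, 19, 1 and 4 for named genes. Only differences that passed in the values reported first could stop passing, and most named differences did not pass there. Under the 60th percentile floor 14 differences of named genes had no value, since the genes were not tested. The cause was not tested for any result that moved or changed direction.

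The 132 genes called for mechanical stress became 9 with no floor, 290 with the 60th percentile floor, 88 over all gene-level probe sets, 404 with eBayes trend, 38 with the matched-pair block, 2 with no covariates, 22 with the skeletal muscle covariate, 0 with the marrow covariate and 2 with the intron control covariate. Leaving out single arrays gave 0 to 124 genes called for the mechanical stress effect. All 132 were also past 1.5-fold. The number of gene lists called for stress, 6, became 0 with camera at an estimated correlation, 1 with fry, 3 with no covariates and 3 with the marrow covariate, and 4 with the matched-pair block or with median-centred arrays, where the B lymphocyte and hedgehog calls ended.

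The gonadectomy effect kept 0 genes called in every alternative but 1, where leaving out the female stress array gave 1, so leaving out single arrays gave 0 to 1. The number of gene lists called for gonadectomy, 6, became 0 with camera at an estimated correlation, 3 with fry and 10 with eBayes trend, and 4 to 11 without single arrays, the 11 without the orchiectomized male under stress.

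For the sex difference, the 7 genes called became 3 with no floor, 16 over all non-control probe sets, 24 with eBayes trend, 13 with array weights, 4 with no covariates, 3 with the skeletal muscle covariate and 3 with the marrow covariate, and 3 to 17 without single arrays. The number of gene lists called for sex, 10, became 0 with camera at an estimated correlation, 1 with fry, 4 with the skeletal muscle covariate and 4 with the marrow covariate.

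For the mechanical stress effect in females, the 4 genes called became 0 with no floor, 43 with the 60th percentile floor, 0 over all non-control probe sets, 88 with median-centred arrays, 12 with quantile normalization again, 193 with eBayes trend and 0 with array weights, and 172 to 697 without single arrays. In males the 0 genes called for the mechanical stress effect became 4 with eBayes trend and 1 with array weights, and 9 to 92 without single arrays. The ovariectomy effect had 13 to 167 genes called without single arrays, and the orchiectomy effect 1 with eBayes trend and 1 to 28 without single arrays. The sex by gonadectomy interaction had 2 genes called without the female control and 3 without the female stress array, and the sex by stress interaction 1 without the ovariectomized female under stress.

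Some differences changed sign, all of genes that did not pass or of lists. With the marrow covariate the stress difference was 0.314 for Acan, -0.303 for Mmp13, -0.0245 for Ctsk and 0.0465 for Tnfrsf11b, and the neutrophil list stood at -0.904 for stress and -0.491 for sex; that covariate holds the neutrophil list itself. With the intron control covariate the stress difference was 0.61 for Esr1, 0.02 for Col2a1 and 0.407 for Adamts5, and the gonadectomy difference 0.0549 for Acp5. Ctsk stood at -0.00888 for gonadectomy with median-centred arrays and at -0.0196 with array weights, and the interferon list at -0.0194 for sex with the 60th percentile floor.

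Over the 8 fits without 1 array each, the differences that changed sign ran, for stress, from -0.336 to 0.188 for Adamts5, from -0.0373 to 0.173 for Mmp13 and from -0.0604 to 0.322 for the skeletal muscle list. For gonadectomy they ran from -0.171 to 0.0922 for Acp5, from -0.144 to 0.0811 for Mmp13, from -0.98 to 0.00793 for Col2a1, from -0.107 to 0.106 for Ctsk, from -0.00749 to 0.162 for Tnfrsf11b and from -0.0497 to 0.475 for Adamts5. For the effects within each sex, whose error both sexes share, leaving out an array of either sex leaves 1 residual degree of freedom and assumes that a lone array varies like the others.

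Of single arrays, the genes past 2-fold became, at 1.5-fold, 4868 for the female stress array, 2464 for the ovariectomized female, 2827 for the ovariectomized female under stress, 1874 for the male stress array, 1729 for the orchiectomized male and 3267 for the orchiectomized male under stress. At 3-fold they became 474, 117, 192, 106, 135 and 224 in the same order. With no floor they became 930 for the ovariectomized female, 696 for the male stress array and 634 for the orchiectomized male, and with the 60th percentile floor 1171, 294, 577, 191 and 217 for the first 5.

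The mean correlation of effects between matched pairs, 0.31 for stress and 0.215 for sex, became 0.212 for stress and 0.128 for sex with no floor, and 0.394 for stress with the 60th percentile floor.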

Other observations

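Every test of an explanation in this part was chosen after the differences had been seen, and 7 gene groups, of glucocorticoid response, brown fat and lipid synthesis, eosinophils, slow and fast fibres and the 2 clock phases, were put together then and each computed for the 3 main effects. The lists of cell types were fixed before the data were examined.

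A group of 14 genes known to be induced by glucocorticoids averaged 0.78 ± 0.65 (SD over genes) under mechanical stress, with no test of the group, since it was assembled from values already seen. Fkbp5 (1.70), Tsc22d3 (1.64), which encodes the anti-inflammatory protein GILZ, Dusp1 (1.44) and Zbtb16 (1.36) were called among all genes. The other 10 did not pass, among them Per1 (1.002), Sgk1 (0.90), Pdk4 (0.88) and Cebpd (0.79), and Nfkbia (-0.26), Mt1 (-0.25) and Mt2 (-0.12) lay below 0. Fkbp5 is also in the sex steroid list and Dusp1 in the immediate early list.

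Genes of brown fat and lipid synthesis varied mostly between single arrays. Their mean over 9 genes was 11.23 on the female control array and 8.21 to 9.48 on the other 7, so that their differences of -0.66 for stress and -0.72 for gonadectomy rest largely on that array, and 0 were called. The 4 eosinophil genes averaged 0.62 for stress, from -0.48 to 1.92 in the pairs, and 0 were called.

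Of muscle genes under stress, 7 of 11 slow fibre genes were called higher and 3 of 12 fast fibre genes lower, a division drawn after these calls were seen and so not itself tested; slow minus fast fibre genes differed by 1.83 ± 0.142 (SE; 1.42 to 2.19 in the 4 pairs). With the intron control median as a covariate the difference was 1.60 ± 0.346 (95% interval 0.497 to 2.70), but limma called 0 genes for this median itself (958 at an unadjusted p under 0.05, against 598 by chance), so the quality that it measures and an effect of stress cannot be told apart, and other differences of array quality were not tested. More attached muscle would raise both kinds. The fast fibre genes averaged -0.27 with an SD over pairs of 0.508, but their median was 0.197, with 8 of 12 above 0 and 4 below. Mb stood at 0.96 and Acta1 at 0.13. More attached muscle and an effect of stress therefore cannot be told apart. A shift of fibre type in muscle left on the condyle may be another source, untested here, although the labels' protocol has soft tissue removed.

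B lymphocyte genes were 1.08 ± 0.213 (SD over 4 pairs) higher after gonadectomy (two-sided exact permutation p = 0.125 for swaps within the pairs, the smallest that 4 pairs allow). More marrow in the samples would raise erythroid and neutrophil genes alike, yet the B lymphocyte shift exceeded the mean of those by 1.43 ± 1.06 (SD over pairs): it was 0.803 or more in each pair, and their mean 0.288 or less. That mean is low largely through the orchiectomized male, without which the neutrophil list stood at -0.06 rather than -0.59, still far below the 1.12 of the B lymphocyte list. A lower share of the main cell type would raise all other markers, yet the shift exceeded that of erythroid, macrophage, endothelial and muscle genes by 1.11 ± 0.412. Both tests argue against these technical explanations as the whole cause, while gonadectomy itself and the hour of collection stay open, untested for these genes.

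Clock genes differed in opposite directions after gonadectomy, though none of the 13 passed (adjusted p = 0.27 to 0.72): 8 that peak when Arntl is low averaged 1.07 and 5 that peak with it averaged -0.84. Their difference was 1.91 ± 0.726 (SD over 4 pairs, 1.19 to 2.92), as tissue collected at another hour of the day would give it, and the hour is not given in the sources used here. Under stress the same difference was 0.57 ± 0.816 (two-sided exact permutation p = 0.25 for swaps within the pairs). A collection hour that differed between gonadectomized and sham-operated mice may therefore be the source, and an effect of gonadectomy on the clock stays open.

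The 8 arrays can be split 4 against 4 in 33 ways that can be fitted beside the other 2 factors, of which only 9 are balanced against those factors as the real split is. These are too few for a share under 0.05. For the genes of stress the real split called 132 and the highest other 0, so 1 split called as many, and the other splits keep the effect of stress at least in part in their error. For the genes of sex the real split called 7, of which 4 are Y-linked and given by the labels, and the highest other 0 (1 split). For gonadectomy limma called 0 (878 at an unadjusted p under 0.05), so all 33 splits call at least as many by construction (highest other 1). For lists chance cannot be excluded for any effect: 10 splits called at least the 6 lists of stress (highest other 10), 12 the 6 of gonadectomy (highest other 10) and 5 the 10 of sex (highest other 12).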
